A study of Mus musculus with 48 samples.

How the data were processed

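Poly(A) RNA from livers of male wild-type mice was sequenced in 48 libraries, 3 in each of 16 groups. Per the labels' protocols, messenger RNA was captured on oligo(dT) beads, second strands were marked with dUTP and digested to keep strand information, and libraries were read as 150 bp pairs on an Illumina NovaSeq. The authors deposited a single table of whole-number counts per gene symbol, not scaled between libraries, with 29331 genes and 1 column per library. The submitters' processing notes name FastQC 0.11.5, STAR 2.5.2b, SAMtools 1.3.1, StringTie 2.2.1 and DESeq2 1.38.1 and the genome build GRCm38, without saying which step each served. The counting step, its strand setting, the gene annotation and the filters are not given in the sources used here, so reads shared between close gene copies, or between genes on opposite strands, cannot be apportioned.

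Each column was tied to a library by the column name that the labels give, and each library to its group by its title. On day 7 there are 12 groups, NC and LPS at each of 6 times of day spaced by 4 h. The other 4 are LPS groups collected at ZT21 before or after that day. Totals ran from 28.2 to 45.3 M counts. Gene positions came from an annotation of GRCm38 matched by symbol, which placed 364 of 365 named genes. No library and no column of the table was left out of the main tests.

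Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr, which left 16544 genes for the day-7 libraries and 16101 for the ZT21 libraries, libraries were scaled by TMM, and edgeR's quasi-likelihood test (robust) was applied with Benjamini-Hochberg adjustment at 0.05. The 36 day-7 libraries entered a model with 1 mean per group and 24 residual degrees of freedom, from which came the LPS effect averaged over the 6 ZTs, the effect at each ZT and the interaction of treatment with ZT. In a second model of these libraries each arm had a 24 h cosine and sine term, which gave the rhythmic genes of each arm and the test of the difference in rhythm. The 18 ZT21 libraries entered a model with 12 residual degrees of freedom, from which came LPS on each of 5 days against NC and a linear trend over days 3 to 11 within LPS. Errors of log2 changes are standard errors of the fit, and CPM are counts scaled to a common library size with TMM factors. Figures show log2 of CPM + 0.1 and were drawn with matplotlib 3.10.9.

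A clock time was read for each library by placing its 19 core clock genes on curves fitted to the NC libraries, by least squares on a grid of 0.1 h, leaving the library itself out where it was NC. Clock times were compared by permutation with 100000 resamples within ZT on day 7 and by exact permutation of 3 against 3 elsewhere.

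Gene lists, 28 in number, were fixed before the data were examined: core clock, clock-controlled output, polyunsaturated fatty acid synthesis, polyunsaturated fatty acid oxidation and eicosanoids, acute-phase response, negative acute-phase, complement, interferon response, NF-kB targets and cytokines, fatty acid oxidation and ketogenesis, lipogenesis, cholesterol synthesis, bile acid synthesis and transport, xenobiotic metabolism, gluconeogenesis and amino acid catabolism, ER stress, heat shock and cold-inducible, immediate early, proliferation, fibrosis and stellate cells, Kupffer cells and macrophages, neutrophils, T, NK and B cells, liver endothelium, cholangiocytes, hepatocytes, blood and erythroid, and other tissues. Some genes stand in more than 1 list, such as Lcn2, Cd14, the C1q genes and Spp1. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists for the averaged effect and over lists and days at ZT21. Counts given as adjusted over the list alone used Benjamini-Hochberg within that list, without adjustment across lists or comparisons.

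Named genes were chosen by a rule written before the data were examined. For the averaged effect it took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 on the log2 CPM scale, the same sign at all 6 ZTs and a symbol that is not a predicted model. For each ZT and day it took the 3 largest each way whose 3 libraries did not overlap between groups, for the interaction and the difference in rhythm the 6 smallest p-values, for the trend the 4 largest each way, and in each comparison all core clock genes and up to 4 members of each other list.

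Alternatives fixed beforehand were DESeq2 1.42.0, RLE scaling, no filter on low counts, the replicate number as a block, a minimum log2 change of 1, all 48 libraries in a single fit, the 6 compared libraries alone, a test of any difference between ZTs and limma-voom for the rhythms, an estimated list correlation, the fry test, each clock gene left out, clock genes at equal amplitude and each library left out in turn. Fits without the 4 day-7 LPS libraries that stood apart, and against NC libraries of the nearest clock time, were added after seeing the data. So were the counts by list in the fit of 48 libraries.

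The tests were run on counts simulated from the real means and library sizes, with 200 genes changed at random per simulation, 100 at each of 2 sizes. For the averaged effect (16192 genes) 68% were recovered at a log2 change of 0.5 and 92% at 1, with 4 false calls. For ZT21 on day 7 (16180 genes) 49% were recovered at 1 and 84% at 2, with 3 false calls, and for the interaction (16180 genes) 21% and 71%, with 6. For rhythms in NC (16190 genes) 59% were recovered at a peak-to-trough range of 1 and 83% at 2, with 6 false calls, and for the difference in rhythm (16190 genes) 28% and 67%, with 3. For day 3 at ZT21 (15740 genes) 64% were recovered at 1 and 86% at 2, with 6 false calls. For the trend (15748 genes) 59% were recovered at 0.125 per day and 86% at 0.25, with 4 false calls. A simulated clock shift of 6 h was read as 5.83 h from 19 simulated genes. In the list test of the averaged effect, 1 of the other lists was called beside the raised list, complement. That list shares the C1q genes with the Kupffer cell list. Simulated genes varied independently and no library stood apart. In the real day-7 libraries the proliferation list had an estimated correlation of 0.81. The recoveries and false calls therefore need not hold for the real libraries, least of all for the lists.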

Results

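Liver RNA was measured in male wild-type mice that received lipopolysaccharide (LPS), a bacterial cell wall component that triggers innate immune signalling, continuously for 7 consecutive days, and in negative control (NC) mice. On day 7, livers of both arms were taken at 6 Zeitgeber times (ZT, hours after lights on), ZT1, ZT5, ZT9, ZT13, ZT17 and ZT21. Further LPS livers were taken at ZT21 on days 3 and 5, during administration, and on days 9 and 11, after it. Each of the 16 groups held 3 libraries, 48 in all. Total counts per library ranged from 28.2 to 45.3 M, with a median of 32.9 M, and 29331 genes were listed. The labels call the libraries of a group biological replicates without stating that each came from a different animal, so the p-values measure the spread between these libraries. All 48 pairs of libraries within a group differed by more than counting noise: the median chi-square value per gene was 1.44 in the closest pair, against 0.455 from counting noise. This does not show that they came from different animals. On days 3, 5 and 9 replicates 1 and 2 lay close together, at 2.47, 1.94 and 1.44. Their values against replicate 3 were at least 5.02, 7.08 and 5.14. On day 11 the closest were replicates 1 and 3, at 2.87. On the first principal component of the 36 day-7 libraries, which held 15.6% of the variance, 4 LPS libraries stood apart. ZT1 replicate 2 scored 62.6, ZT13 replicate 2 scored 81.8, and ZT21 replicates 1 and 3 scored 63.2 and 72.9, and the next library scored 27.6. Fits without these 4 libraries were added after seeing the data.

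The first comparison asked what 7 days of LPS changed in the liver when time of day was set aside, as the mean of the 6 differences between LPS and NC. Among the genes with the largest changes, a macrophage receptor gene and antibody genes were higher in LPS livers, and 4 genes for major urinary proteins, pheromone carriers that male mouse liver secretes, were lower. Marco, a scavenger receptor of macrophages (GRCm38 chromosome 1, 120474538 to 120505024), rose by 2.47 ± 0.34 on the log2 scale (SE; adjusted p = 0.000217; higher in 18 of 18 LPS libraries), from 3.13 ± 1.63 CPM (counts scaled to a common library size) in NC to 22.2 ± 43.9 CPM in LPS (mean ± SD, n = 18 each). Cyp2b9, a cytochrome P450 with more transcript in female than in male mouse liver (chromosome 7, 26173411 to 26210661), rose by 3.65 ± 0.57 (adjusted p = 0.000642; 18 of 18 libraries), from 1.39 ± 1.67 to 33.7 ± 63.1 CPM. The antibody genes Ighg2b and Igkc rose by 2.40 ± 0.39 and 1.64 ± 0.26 (adjusted p = 0.000753 for each), both in 18 of 18 libraries. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1545 of 16544 tested genes passed, 915 higher and 630 lower.

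Among the other genes with the largest rises, the histone gene H4c8 gained 2.19 ± 0.21 (adjusted p = 5.63e-07; 17 of 18 libraries) and Gtse1, expressed in dividing cells, gained 1.55 ± 0.24 (16 of 18). Slc22a27, an organic anion transporter, rose by 2.97 ± 0.54 (16 of 18) and Cyp17a1, a steroid hydroxylase, by 2.01 ± 0.45 (15 of 18). The acute-phase genes A2m and Lcn2 rose by 2.86 ± 0.89 (adjusted p = 0.0444) and 2.78 ± 0.64 (adjusted p = 0.0103). Both were dominated by LPS ZT1 replicate 2, which held 25727 counts of A2m against 53 in the next LPS library of day 7 and 209849 of Lcn2 against 3699. Without that library A2m stood at 1.47 (adjusted p = 0.0139) and Lcn2 at 1.24 (adjusted p = 0.0329). Of the 36 fits that each left out 1 library, A2m passed in 6 and Mup18 in 12. The largest falls were in major urinary protein genes: Mup17 fell by 2.03 ± 0.59, Mup15 by 2.02 ± 0.55, Mup21 by 1.46 ± 0.33 and Mup18 by 1.15 ± 0.36, in 16 to 18 of 18 libraries, whereas Mup7 did not pass (-1.42, adjusted p = 0.149). Csad, an enzyme of taurine synthesis, fell by 1.40 ± 0.23 and the small heat shock gene Hspb1 by 1.05 ± 0.17, from 34.6 ± 14.9 to 16.4 ± 7.78 CPM. Serpina1e, Col27a1, Ugt1a10 and Wnk4 fell by 1.01, 0.93, 0.78 and 0.74. Without NC ZT9 replicate 3, Mup17 (-1.62, adjusted p = 0.0725), Mup15 (-1.64) and Mup18 (-1.04) no longer passed. Mup, Cyp2b, Slc22a, Serpina1, Ugt1a, histone H4 and antibody genes have close copies or shared exons, and how reads of such families were assigned is not stated, so the split between members is uncertain.

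Without the 4 libraries that stood apart, 521 genes passed in place of 1545, 400 of them among those 1545. Cyp2b9 (2.04), Marco (1.73), Ighg2b (1.85), Igkc (1.12), H4c8 (2.36), Slc22a27 (1.17), Gtse1 (1.10), Mup21 (-1.06), Csad (-1.08), Hspb1 (-0.80), Serpina1e (-0.66), Col27a1 (-0.62) and A2m (1.56) still passed. By contrast, Lcn2 (0.77), Cyp17a1 (0.52), Mup17 (-1.58), Mup15 (-1.58), Mup18 (-0.76), Ugt1a10 (-0.67) and Wnk4 (-0.50) did not.

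**Figure D1:**
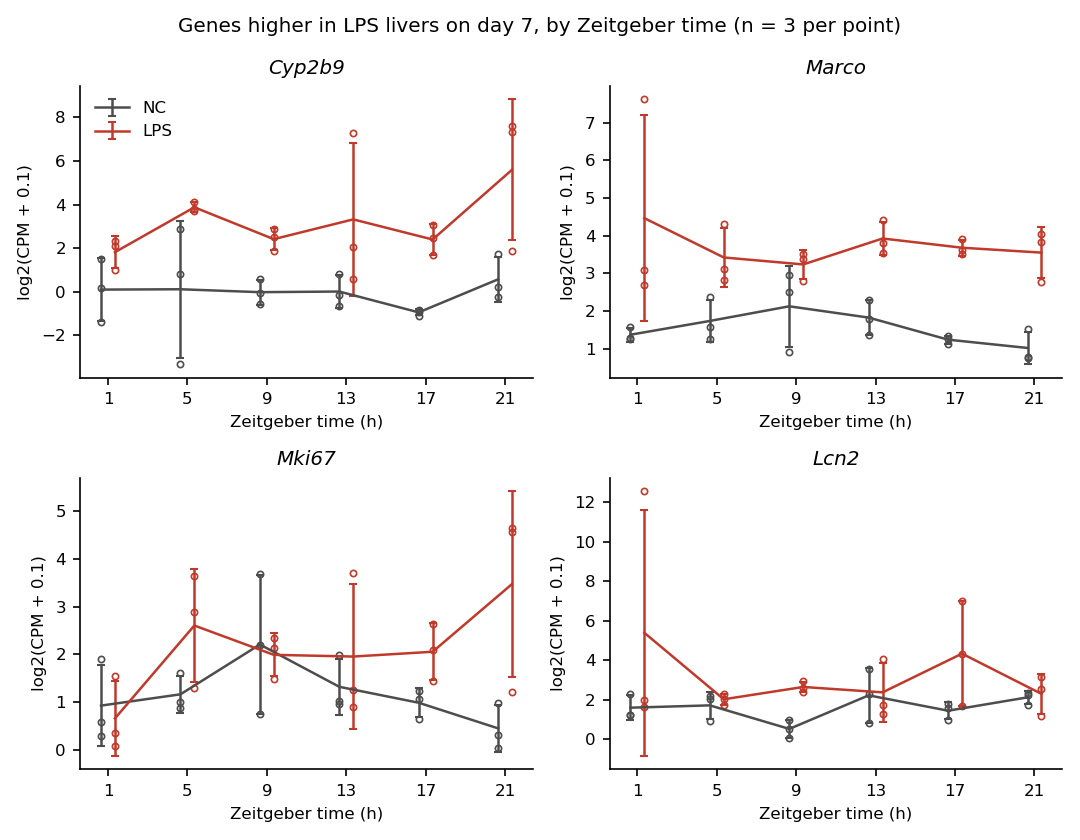
Level of Cyp2b9, Marco, Mki67 and Lcn2 (log2 of CPM + 0.1, vertical axis) by Zeitgeber time in hours (horizontal axis) in NC (grey) and LPS (red) livers on day 7; open points are libraries, and lines join means of the 3 libraries with their SD. Marco is higher in LPS by 2.47 on the log2 scale averaged over the 6 times, and the single high Lcn2 point at ZT1 is the library with 209849 counts of that gene.

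Of the 28 lists fixed beforehand 12 passed for the averaged effect, among them those of neutrophils and proliferation. With an estimated correlation 0 passed, by fry 0 passed, and 21 of 100 splits of the same libraries gave as many lists, so chance is not excluded for this number. Of 12 neutrophil markers tested, 8 rose and none fell (9 adjusted over the list alone), among them S100a9 at 2.73 ± 0.55, S100a8 at 2.64 ± 0.54 and the granule protease Elane at 3.44 ± 0.67. In NC libraries the mean level of this list ran from -2.78 to -0.77 on the log2 CPM scale. From so low a level falls could hardly be called, and the rises start from few reads. Of 24 proliferation genes, 17 rose (23 adjusted over the list alone). Among them were the mitotic genes Ccnb2 at 1.28 ± 0.25 and Cdc20 at 1.39 ± 0.36. In a competitive list test (camera, preset correlation 0.01) the adjusted p was 1.12e-04 for neutrophil markers and 1.04e-07 for proliferation, and 0.586 was the adjusted p of both with an estimated correlation. Among the libraries that did not stand apart, the median change was 2.47 over 11 neutrophil markers and 0.40 over 24 proliferation genes. With all libraries it was 2.65 and 0.94. Of 20 Kupffer cell and macrophage markers 2 rose, Marco and Lyz2 (4 adjusted over the list alone; camera adjusted p = 0.0395, and 0.731 as the adjusted p with an estimated correlation). Among 18 T, NK and B cell markers 4 rose, Igkc, Ighm, Jchain and Gzma (5 adjusted over the list alone; adjusted p = 0.0369, and adjusted p = 0.586 with an estimated correlation). Of 14 liver endothelial markers 4 rose (6 adjusted over the list alone; adjusted p = 1.83e-05), with Lyve1 at 0.77 and Stab1 at 0.29. Of 18 fibrosis and stellate cell markers 1 rose, Spp1 at 0.55 (12 adjusted over the list alone; adjusted p = 3.28e-05). With an estimated correlation both endothelial and fibrosis lists had an adjusted p of 0.586. Without the 4 libraries their median changes were 0.141 and 0.243, against 0.195 and 0.403 with all libraries.

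Calls among acute-phase genes were rises and calls among interferon response genes were falls. Of 29 acute-phase genes 7 rose and none fell (9 adjusted over the list alone), with Orm3 at 2.00, Orm2 at 1.81 and the LPS co-receptor Cd14 at 1.48, but the list as a whole did not pass (camera adjusted p = 0.141). In the fit without the 4 libraries apart 2 of 29 passed, with a median change of -0.04 over the list. The mean level of the list, on the log2 CPM scale, was 11.6 in LPS ZT1 replicate 2 and at most 7.79 in the other day-7 libraries. Of 34 interferon response genes none rose and 8 fell (1 rose and 12 fell adjusted over the list alone), with the antiviral gene Mx2 at -0.63 and the transcription factor gene Irf7 at -0.39. The list lay lower at an adjusted p of 1.13e-05, and at adjusted p = 0.586 with an estimated correlation. In the fit without the 4 libraries apart 3 of its members fell (camera adjusted p = 3.96e-07). Of 24 complement genes 3 fell, C9 at -0.59, C8b at -0.37 and Hc at -0.27 (adjusted p = 0.0374, and adjusted p = 0.586 with an estimated correlation). Among 22 ER stress genes 2 fell, Dnajc3 at -0.28 and Hsp90b1 at -0.29 (6 adjusted over the list alone; adjusted p = 0.00331). Among 15 heat shock and cold-inducible genes 3 fell, Hspb1, Hsp90aa1 and Hsp90ab1 (4 adjusted over the list alone; adjusted p = 0.0113). For ER stress and heat shock genes the adjusted p with an estimated correlation was 0.586. NF-kB targets and cytokines had 2 rises in 22, Cd14 and Ccl5. Blood and erythroid genes had 3 in 10 (Pf4, Klf1 and Slc4a1), cholangiocyte markers 1 in 10 (Spp1), and negative acute-phase genes 1 fall in 10 (Serpina1e). No member of the immediate early, hepatocyte or other-tissue lists passed, with 18, 15 and 3 tested.

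Metabolic lists held few called genes. Gluconeogenesis and amino acid catabolism had 5 rises in 22, with the histidine-degrading enzyme gene Hal at 0.31 and Fbp1 at 0.20 (8 rises and 1 fall adjusted over the list alone; camera adjusted p = 0.0115, and adjusted p = 0.586 with an estimated correlation). Lipogenesis had 1 rise in 21, the lipogenic transcription factor gene Srebf1 at 0.42 (adjusted p = 0.0395, and adjusted p = 0.723 with an estimated correlation). Synthesis of polyunsaturated fatty acids, which the title of the study concerns, had 2 rises in 16: the desaturase genes Fads2 (chromosome 19, 10062765 to 10101746) at 0.61 ± 0.15 (adjusted p = 0.0127; 14 of 18 libraries) and Fads1 (chromosome 19, 10182888 to 10196877) at 0.37 ± 0.11 (adjusted p = 0.0348; 12 of 18 libraries). Fads2 moved from 656 ± 238 to 1060 ± 685 CPM. With the 4 libraries apart left out, Fads2 stood at 0.35 (adjusted p = 0.0584) and Fads1 at 0.15 (adjusted p = 0.298), and no member of the list passed. The list as a whole did not pass (camera adjusted p = 0.466). Fatty acid oxidation had 2 rises in 31, Ppargc1a at 0.55 and Cpt1a at 0.33. Oxidation of polyunsaturated fatty acids had 3 rises and 2 falls in 30, bile acid genes 2 rises in 21, cholesterol synthesis 1 in 24 and xenobiotic metabolism 3 rises and 2 falls in 32. When the 4 libraries apart were left out, the median change was -0.0359 for the Kupffer cell, 0.0289 for the lipogenesis and -0.0715 for the heat shock list. With all libraries these lists stood at 0.143, 0.139 and -0.104. For 3 other lists the median change was larger in size without the 4 libraries: 0.111 for fatty acid oxidation, -0.202 for cholesterol synthesis and 0.469 for blood and erythroid genes. With all libraries it was 0.0595, -0.112 and 0.108. The estimated correlation was not run without the 4 libraries. With all libraries it gave these 3 lists a camera adjusted p of 0.811, 0.811 and 0.586.

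Clock genes changed in mean level in both directions on day 7. Of 19 core clock genes 3 rose and 2 fell (5 and 4 adjusted over the list alone). The activator genes Arntl (chromosome 7, 113207465 to 113314126) and Clock fell by 0.61 ± 0.17 (adjusted p = 0.0247) and 0.39 ± 0.06 (adjusted p = 0.000451), each lower in 15 of 18 libraries. The repressor genes Nr1d1 (chromosome 11, 98767932 to 98775333), Per1 (chromosome 11, 69095217 to 69109960) and Bhlhe40 rose by 0.84 ± 0.19, 0.65 ± 0.21 and 0.44 ± 0.10. Cry1, the repressor named in the title (chromosome 10, 85131700 to 85185064), went from 23.9 ± 14.6 to 18.2 ± 9.95 CPM, a log2 difference of -0.31 ± 0.11 that did not pass (adjusted p = 0.0582; lower in 13 of 18 libraries). Dbp (0.83), Nfil3 (-0.44), Nr1d2 (0.40), Per2 (0.28) and Per3 (0.28) did not pass either. Of 18 clock-controlled output genes 3 rose, Noct at 0.68, Rgs16 at 1.24 and Por at 0.41 (4 adjusted over the list alone; camera adjusted p = 0.272). In the fit without the 4 libraries apart, Clock (-0.30) and Bhlhe40 (0.45) still passed, and Nr1d1 (0.62), Per1 (0.41) and Arntl (-0.39) did not. Per1 kept its call in 5 of the 36 fits that left out 1 library. Removing LPS ZT1 replicate 2 took Per1 to 0.40 (adjusted p = 0.0786), and removing LPS ZT13 replicate 2 took Arntl to an adjusted p of 0.0519. Arntl and Nr1d1 share exons with genes of the opposite strand, Gm45355 and Thra, so part of their counts is uncertain.

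The next comparison asked at which times of day LPS and NC livers differed. In the fit of all day-7 libraries the calls were most numerous at ZT21 and ZT13: 1473 genes passed at ZT21 (913 higher, 560 lower), 526 at ZT13 (306 and 220), 75 at ZT9 (52 and 23), 59 at ZT1 (52 and 7), 2 at ZT5 and 0 at ZT17. For ZT17, edgeR's quasi-likelihood test gave 1475 genes at an unadjusted p under 0.05, and DESeq2 called 52. DESeq2 split its calls as 250 higher and 70 lower at ZT1, 30 and 20 at ZT5, and 168 and 116 at ZT9. At ZT21 without the 4 libraries apart, which leaves 1 LPS library there, 2 genes passed, against 394 each at ZT9 and ZT13, 51 at ZT17, 28 at ZT5 and 0 at ZT1. With only the 6 libraries of a time in the fit, 0 genes passed at ZT1, ZT13 and ZT21, 67 at ZT9, 131 at ZT5 and 151 at ZT17, so the order of the times depends on the fit. Most removals of 1 library moved the count at ZT1 or ZT9: at ZT1 from 0 without NC replicate 1, NC replicate 2 or LPS replicate 2 to 563 without LPS replicate 1, and at ZT9 to 0 without NC replicate 2 and 3 without LPS replicate 2. At ZT13 the count was 111 without LPS replicate 2, 150 without NC replicate 3 and 327 without NC replicate 2. At ZT21 it was 64 without LPS replicate 1, 259 without LPS replicate 3, 197 and 615 without NC replicates 2 and 3, and 2875 without LPS replicate 2.

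At ZT21, close to the end of the dark phase, most proliferation genes and part of the lipid synthesis genes were higher in LPS livers and part of the gluconeogenic genes were lower. The largest rises were in Slc22a27 (6.99 ± 1.48), Cyp2b9 (6.16 ± 1.43) and Uhrf1, a gene of DNA replication and methylation upkeep (5.01 ± 0.99). The largest falls were in Dct (-2.42), Ugt1a10 (-2) and the nicotinamide methyltransferase Nnmt (-1.96). Of 24 proliferation genes 22 rose (24 adjusted over the list alone). Of 24 cholesterol synthesis genes 8 rose (18 adjusted over the list alone), of 21 lipogenesis genes 7 rose (11 adjusted over the list alone) and of 16 polyunsaturated fatty acid synthesis genes 4 rose (7 adjusted over the list alone). Of 22 gluconeogenesis and amino acid genes 9 fell (15 adjusted over the list alone). In the fit of the ZT21 libraries of all days, the same comparison called 0 of 24 cholesterol synthesis genes, and 4 rises and 1 fall in lipogenesis. Of the clock genes at ZT21, Arntl (-1.53 ± 0.39), Clock (-0.73) and Cry1 (-0.82 ± 0.26, adjusted p = 0.0439) were lower, and Dbp (2.92 ± 0.70), Nr1d1 (1.75) and Nr1d2 (1.18) were higher. Without LPS ZT21 replicates 1 and 3, none of the genes named here passed at ZT21.

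At ZT13 the antibody genes Ighg2b (3.61 ± 0.99) and Igkc (3.21 ± 0.68) were among the genes with the largest rises. The largest falls were in Phospho1 (-3.27 ± 0.71), Csad (-2.06) and the nuclear receptor corepressor Lcor (-1.20). Of 14 liver endothelial markers 8 rose at ZT13 (13 adjusted over the list alone) and of 22 gluconeogenesis and amino acid genes 7 rose (11 adjusted over the list alone). Without LPS ZT13 replicate 2, Ighg2b stood at 2.85 and Igkc at 1.88, and none of these 5 genes passed. At ZT1 the rises were led by Marco (4.82 ± 0.89), Cd14 (4.50 ± 0.93) and the signalling adaptor Tifa (4.01 ± 0.79), and 11 of 29 acute-phase genes rose (26 adjusted over the list alone). These rested on LPS ZT1 replicate 2, without which Marco was at 1.55, Cd14 at 0.37 and Tifa at 0.47, none past the threshold. At ZT9 the phosphate transporter Slc34a2 (3.5 ± 0.76), H4c8 (2.79 ± 0.53) and the haem synthesis gene Alas1 (2.26 ± 0.46) rose. The immediate early nuclear receptor Nr4a1 (-2.25), Plxna2 (-1.55) and Spaca6 (-1.42) fell. Each of these ZT9 calls was lost in at least 3 of the 6 fits that left out 1 library, those of Slc34a2 and Nr4a1 in 6. At ZT5 the chaperone gene Hspa8 (chromosome 9, 40800984 to 40810087) rose by 1.08 ± 0.16 (adjusted p = 0.00126), and by 0.95 with an adjusted p of 0.0541 without NC replicate 3.

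Whether the LPS effect itself depended on time of day was tested by the interaction of treatment with ZT, which 282 genes passed. The predicted gene Gm15459 had the smallest p-value (adjusted p = 0.00134), and single genes of unlike function came next. Hspa8 (adjusted p = 0.00137) had LPS effects from -0.41 at ZT17 to 1.08 at ZT5. The mitochondrial glycerol phosphate dehydrogenase Gpd2 (adjusted p = 0.00274) had effects from -0.63 at ZT13 to 1.39 at ZT21, and Hal (adjusted p = 0.00338) from -0.45 at ZT9 to 1.11 at ZT13. P4ha1, a collagen hydroxylase, passed at the same adjusted p as Hal (0.00338), and Nrp1, a vascular co-receptor, and Arhgef37 passed too. Of the lists, 9 of 22 gluconeogenesis genes (17 adjusted over the list alone), 6 of 24 cholesterol synthesis genes (21 adjusted over the list alone), 4 of 15 heat shock genes (12 adjusted over the list alone), 3 of 18 clock output genes (11 adjusted over the list alone) and 2 of 29 acute-phase genes (25 adjusted over the list alone) passed. No core clock gene passed (6 of 19 adjusted over the list alone), the smallest adjusted p being that of Clock at 0.0629. Of the 36 removals of 1 library, 22 moved this count by over 1.5 times, between 68 without LPS ZT21 replicate 3 and 1429 without LPS ZT21 replicate 2, DESeq2 called 1725, and without the 4 libraries apart 108 genes passed. Of the lists above, 3 of 22 gluconeogenesis, 1 of 24 cholesterol synthesis, 1 of 15 heat shock, 0 of 18 clock output and 0 of 29 acute-phase genes then passed.

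Rhythms of 24 h were then fitted in each arm to ask whether the liver clock was rhythmic under LPS. In both arms it was: 18 of 19 core clock genes were rhythmic in NC and in LPS, the exception being Rora. Arntl peaked at ZT 2.89 ± 0.48 h in NC and 3.46 ± 0.38 h in LPS (peak ± SE), and Nr1d1 at 12.1 and 12 h. Dbp peaked at 14.5 and 14.9 h, Per1 at 17.8 ± 0.40 and 16.2 ± 0.77 h, Per2 at 19.4 ± 0.41 and 18.0 ± 0.44 h, and Cry1 at 0.0592 and 0.0139 h. The peak-to-trough range of Nr1d1 was 6.43 in NC and 4.33 in LPS on the log2 scale, and that of Cry1 was 2.47 and 1.93. Over all genes 3719 were rhythmic in NC and 2646 in LPS, counts that do not by themselves show a difference between arms. A test of any difference between the 6 ZTs turned their order, with 3135 in NC and 4188 in LPS.

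**Figure D2:**
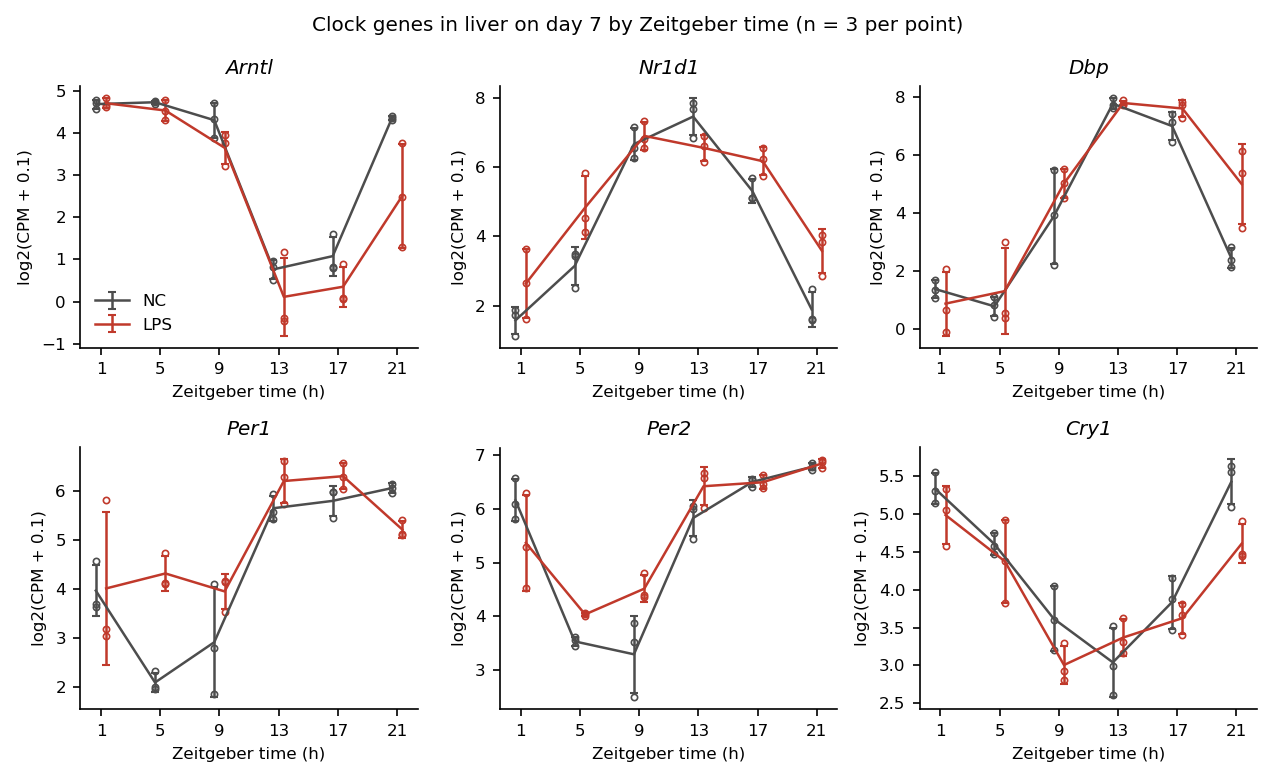
Level of 6 clock genes (log2 of CPM + 0.1, vertical axis) by Zeitgeber time in hours (horizontal axis) in NC (grey) and LPS (red) livers on day 7; open points are libraries, and lines join means of the 3 libraries with their SD. The curves of both arms rise and fall over the day, with fitted Arntl peaks at 2.89 and 3.46 h.

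The test of the difference in rhythm passed for 28 genes and for no core clock gene, the smallest adjusted p among them being that of Nr1d1 at 0.131. The genes that passed included Cyp2r1, a vitamin D 25-hydroxylase (chromosome 7, 114549682 to 114562972; adjusted p = 0.0167), which peaked at 8.21 h in NC and 23.8 h in LPS. Others were the nucleotidase Nt5c2 (adjusted p = 0.0229), which peaked at 11.7 and 20.5 h, and Cntrl (adjusted p = 0.0231), Tedc2, Spaca6 and Igsf8 (each adjusted p = 0.0288). Adjusted over the list alone, 16 of 24 cholesterol synthesis genes, 14 of 29 acute-phase genes, 7 of 24 proliferation genes, 4 of 18 clock output genes and 2 of 19 core clock genes passed this test. Rhythmic members in NC and LPS numbered 14 and 2 of 15 heat shock genes, 4 and 20 of 24 cholesterol synthesis genes, 0 and 21 of 29 acute-phase genes, and 21 and 9 of 34 interferon genes. No member of these lists passed the test of the difference at the main threshold. In the fit without the 4 libraries apart, the numbers were 15 and 2 of the heat shock, 9 and 13 of the cholesterol synthesis, 11 and 13 of the acute-phase and 25 and 7 of the interferon genes. Of 36 removals of 1 library, 12 moved the count of 28 by over 1.5 times, between 1 without LPS ZT21 replicate 1 and 72 without LPS ZT21 replicate 2. In that fit without the 4 libraries apart 6 genes passed, and DESeq2 called 302.

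To give each library a single clock reading, its 19 clock genes were placed on the NC curve and compared with its labelled time. On day 7 the LPS libraries read 0.256 ± 1.51 h past their labels and the NC libraries 0.0111 ± 1.12 h (SD, n = 18 each), a difference of 0.244 h (2-sided permutation p = 0.524 within ZT; adjusted p = 0.577 over 11 tests). The mean covers differences of opposite sign, 1.1, 1.17, 0.93 and 1.13 h at ZT1, ZT5, ZT9 and ZT13 and -0.87 and -2 h at ZT17 and ZT21, with adjusted p from 0.471 to 0.577. At ZT21 the 3 LPS libraries of day 3 read 9.43 ± 0.42 h past the label, with a range of 9.1 to 9.9 h, and those of day 5 read 5.27 ± 1.93 h past it, with a range of 4.1 to 7.5 h. The 3 NC libraries read 0.60 ± 0.95 h past it. On days 9 and 11 the values were 1.63 ± 0.92 and 1.27 ± 1.16 h, and on day 7 the LPS value was -1.40 ± 1.25 h. Days 3 and 5 against NC each gave an exact 2-sided permutation p of 0.10, the smallest that 3 against 3 allow, and days 9 and 11 gave 0.30 and 0.60 (adjusted p = 0.471 for days 3, 5 and 9 and 0.6 for day 11). From 200 rhythmic genes outside the clock lists, the day-3 and day-5 libraries read 9.13 ± 0.93 and 4.93 ± 1.62 h past the label. Without Nr1d1 among the clock genes, the day-7 difference turned to -0.15 h.

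**Figure D3:**
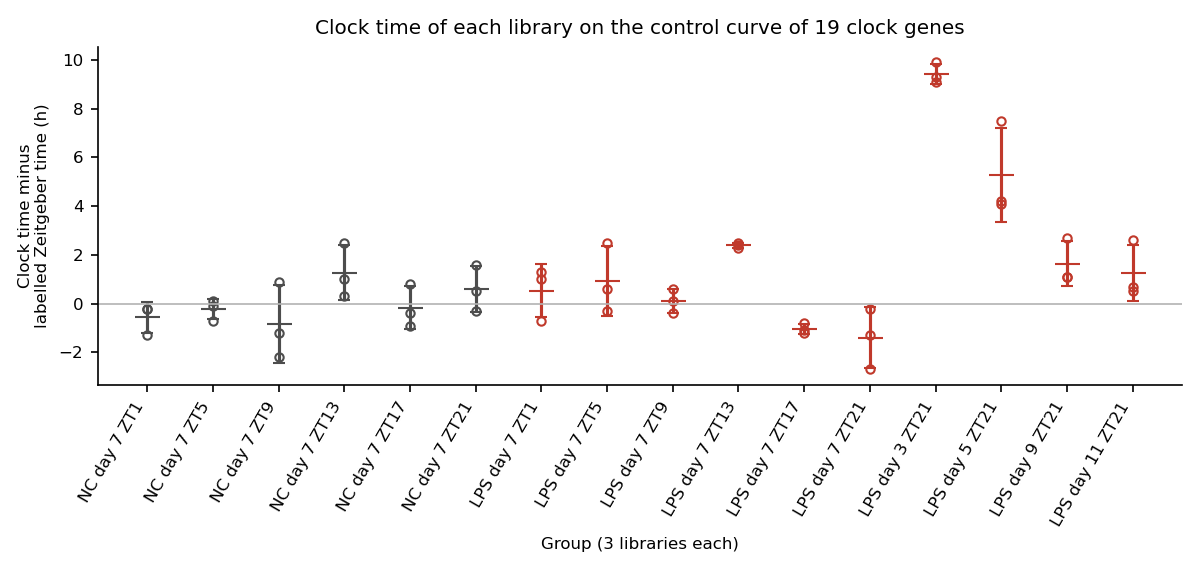
Clock time minus labelled Zeitgeber time in hours (vertical axis) for each of the 48 libraries (open points) by group (horizontal axis), NC in grey and LPS in red; dashes and bars are group mean and SD of 3 libraries. The ZT21 libraries of days 3 and 5 lie 9.43 and 5.27 h past the label on average, and those of days 9 and 11 lie 1.63 and 1.27 h past it.

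The ZT21 series asked how the liver changed over the days of LPS and after it ended. NC livers at ZT21 were taken on day 7 alone, so day and treatment cannot be separated and all 5 contrasts share the same 3 control libraries. On day 3 most macrophage, neutrophil and acute-phase genes of the lists were higher than in control livers of ZT21, and most clock output genes were lower. Marco rose by 5.79 ± 0.40 (adjusted p = 9.35e-07), from 1.99 ± 0.674 to 111 ± 29.3 CPM (SD, n = 3 each), and S100a9, a neutrophil calcium-binding protein (chromosome 3, 90692632 to 90695721), by 5.78 ± 0.76. The acute-phase gene Orm2 rose by 5.00 ± 0.43, from 11 ± 0.938 to 355 ± 70.1 CPM. Of 16101 tested genes 3303 passed, 1652 higher and 1651 lower; without NC replicates 2 and 3 the counts were 2109 and 2182.

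Of 29 acute-phase genes 17 rose on day 3 and none fell (19 adjusted over the list alone; camera adjusted p = 1.11e-08, and adjusted p = 0.00785 with an estimated correlation), the one list that also passed with an estimated correlation. Of 20 Kupffer cell and macrophage markers 17 rose (18 adjusted over the list alone), with Adgre1 and Lyz2 at 2.70 and Csf1r at 1.53. Of 13 neutrophil markers 12 rose (13 adjusted over the list alone). In the 3 NC libraries of ZT21 the mean level of neutrophil markers was -2.36, -2.78 and -2.66 on the log2 CPM scale, so falls could hardly be called. Of 22 NF-kB targets and cytokines 13 rose (15 adjusted over the list alone), with Cxcl1 at 2.61 and Il1b at 2.56. Their camera adjusted p was 3.95e-16, 2.16e-07 and 1.11e-08, and with an estimated correlation adjusted p = 0.0928, 0.205 and 0.0891. Of 19 T, NK and B cell markers 11 rose (14 adjusted over the list alone; adjusted p = 2.03e-06, and adjusted p = 0.162 with an estimated correlation), with Gzma at 4.74 and Ms4a1 at 3.58. Of 18 fibrosis and stellate cell markers 8 rose (11 adjusted over the list alone; adjusted p = 0.000243, and adjusted p = 0.37 with an estimated correlation). Of 15 hepatocyte markers 6 fell (8 adjusted over the list alone; adjusted p = 0.00219, and adjusted p = 0.229 with an estimated correlation), with Tat at -1.55 and Fabp1 at -1.09.

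In fat and sugar metabolism on day 3, 13 of 31 fatty acid oxidation and ketogenesis genes fell (16 adjusted over the list alone), with Angptl4 at -3.99 and the carnitine carrier Slc25a20 at -0.98. In lipogenesis 8 of 21 genes fell, with Thrsp at -4.06. Of 16 polyunsaturated fatty acid synthesis genes 5 fell (8 adjusted over the list alone), with Acsl1 at -1.15. Of 24 cholesterol synthesis genes 5 fell. Camera adjusted p was 3.55e-08, 1.34e-06, 0.000137 and 3.22e-05 for these 4 lists, and with an estimated correlation adjusted p = 0.205, 0.267, 0.229 and 0.469. Gluconeogenesis and amino acid genes showed 8 falls and 1 rise in 22 (adjusted p = 0.000802, and adjusted p = 0.417 with an estimated correlation). Heat shock and cold-inducible genes showed 8 falls and 1 rise in 15, with Hspa1a at -3.22 and the cold-inducible Cirbp at 0.88 (adjusted p = 0.000821, and adjusted p = 0.385 with an estimated correlation). Mup17 fell by 5.2 ± 1.31 and the lysolipid transporter Mfsd2a by 4.74 ± 0.96.

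Clock genes on day 3 at ZT21 were far from the control level: Per1 fell by 4.60 ± 0.40 (adjusted p = 8.57e-06), from 66.3 ± 4.5 to 2.74 ± 0.778 CPM, Ciart by 3.41, Per3 by 3.11, Per2 by 2.64, Tef by 2.11 and Cry1 by 0.97 ± 0.23 (adjusted p = 0.00808). Nr1d1 and Npas2 rose by 3.91 and 4.37. In all 2 rose and 10 fell of 19 (the same counts adjusted over the list alone; camera adjusted p = 0.000294, and adjusted p = 0.101 with an estimated correlation). Of clock output genes 13 fell and 1 rose of 18 (13 and 2 adjusted over the list alone; adjusted p = 2.34e-08, and adjusted p = 0.0928 with an estimated correlation), with Usp2 at -4.82 ± 0.48 and Lpin1 at -4.49. Because the clock of these libraries read 6.43 h, an added comparison used NC libraries of ZT5 in place of ZT21, in a fit of all 48 libraries; 1233 genes then passed, against 3258 with NC of ZT21 in the same fit. In it Marco (5.01), S100a9 (5.04), Adgre1 (2.18) and Nr1d1 (2.65) still rose, Per1 (-0.61, adjusted p = 0.56) and Cry1 (-0.12) did not pass. Per2, Cry2, Hlf and Ciart turned to 0.62, 0.0202, 0.14 and 0.47. The NC group was chosen by the reading of the core clock genes, so their nearness to it follows in part from that choice. Of the interferon genes 12 fell, against 1 with NC of ZT21. Rises numbered 10 of 20 macrophage, 9 of 13 neutrophil, 3 of 29 acute-phase, 2 of 23 NF-kB and 2 of 19 T, NK and B cell genes, against 17, 11, 4, 12 and 11 with NC of ZT21 in the same fit. Acute-phase calls were thus lost mostly with the change of fit, and the median change of that list was 0.76 against ZT5 and 0.66 against ZT21 controls. Of clock output genes 4 fell and 1 rose, of hepatocyte markers 0 passed, and of gluconeogenesis genes 1 fell and 3 rose, against 12 and 2, 3 falls, and 7 and 1. Fatty acid oxidation, lipogenesis and cholesterol synthesis genes showed 8, 7 and 7 falls, against 10, 7 and 6. The heat shock list turned round, from 1 rise and 10 falls in 15 with a median change of -0.86 to 5 rises and 0 falls with a median change of 0.34.

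On day 5 most neutrophil markers were higher than in control livers of ZT21. S100a9 rose by 5.30 ± 0.76, Cyp2b9 by 5.70 ± 1.57 and Slc34a2 by 5.16 ± 0.56. Mup17 fell by 4.95, the carboxylesterase gene Ces2b fell by 4.24 and the gluconeogenic gene Pck1 fell by 4.23. Marco stood at 19.4 ± 4.31 CPM and had risen by 3.28. Of 13 neutrophil markers 10 rose (12 adjusted over the list alone) and of 22 NF-kB targets 10 rose and 1 fell (camera adjusted p = 3.17e-06 and 2.74e-05, and with an estimated correlation adjusted p = 0.229 and 0.119). Of 34 interferon genes 7 rose, with Gbp7 at 1.00 and Irf1 at 0.92 (8 adjusted over the list alone; adjusted p = 0.00163, and adjusted p = 0.5 with an estimated correlation). Lipogenesis showed 5 rises and 1 fall in 21, with Elovl6 at 2.88 and Srebf1 at 1.42 (9 and 2 adjusted over the list alone; adjusted p = 0.00703, and adjusted p = 0.469 with an estimated correlation). Fatty acid oxidation showed 8 falls and 2 rises in 31 (adjusted p = 0.000432, and adjusted p = 0.37 with an estimated correlation). Per1 fell by 2.88, Ciart by 2.80, Per3 by 2.01 and Nr1d2 by 1.98, Npas2 rose by 5.06, and Cry1 was at 0.11 (adjusted p = 0.81). The calls of Cyp2b9, Mup17 and Ces2b each held in 1 of the 6 fits that left out 1 library. Of 1865 genes that passed, 951 were higher and 914 lower. The count was 610, 1080 and 1240 without NC replicates 2, 3 and 1, 663 and 611 without day-5 replicates 1 and 2, and 526 against NC libraries of ZT1, nearest to the clock reading of 2.23 h, in the fit of 48 libraries that gave 1924 with NC of ZT21. In that added comparison 2 of 13 neutrophil markers, 0 of 23 NF-kB targets, 0 of 34 interferon genes and 7 of 21 lipogenesis genes rose, against 6, 3, 7 and 7 with NC of ZT21 in the same fit. The median change of the neutrophil list was 3.73 against 5.30. Of interferon genes 2 fell, against 0, and of 31 fatty acid oxidation genes 0 fell, against 6.

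On day 7, with the same 6 libraries now fitted beside the other ZT21 livers, most proliferation genes were higher. Proliferation genes rose in 22 of 24 (24 adjusted over the list alone; camera adjusted p = 7.44e-12, and adjusted p = 0.362 with an estimated correlation), with Ccna2 at 3.52 and the replication helicase gene Mcm3 at 3.20. Fibrosis and stellate cell markers rose in 10 of 18 (11 adjusted over the list alone; adjusted p = 6.36e-09, and adjusted p = 0.205 with an estimated correlation), with the collagen genes Col1a1 at 2.06 and Col3a1 at 1.69. In the day-7 fit the same comparison called 3 of these 18 (9 adjusted over the list alone). Fads2 rose by 1.79 ± 0.37 (adjusted p = 0.0131) and Fads1 by 1.23 ± 0.31 (adjusted p = 0.0248). The list of polyunsaturated fatty acid synthesis had 3 rises in 16 (5 adjusted over the list alone; adjusted p = 0.0198, and adjusted p = 0.417 with an estimated correlation). Acute-phase genes showed 6 falls and 1 rise in 29, with Saa1 at -2.05 and Lbp at -1.34 (adjusted p = 0.00306, and adjusted p = 0.109 with an estimated correlation), and 1 fall in the day-7 fit. ER stress genes showed 5 falls in 22 and gluconeogenesis genes 10 falls in 22 (adjusted p = 4.21e-06 and 2.72e-08, and with an estimated correlation adjusted p = 0.369 and 0.229). Hepatocyte markers showed 5 falls in 15, neutrophil markers 7 rises in 13 and macrophage markers 3 rises in 20. Their camera adjusted p was 0.00321, 0.00117 and 0.00171, and with an estimated correlation 0.229, 0.37 and 0.417. In the day-7 fit these lists had 3 falls in 15, 2 rises in 12 and 1 rise in 20. Of 1516 genes that passed, 2 also did so without LPS replicates 1 and 3, the libraries apart. Leaving out one library gave 164 and 192 without LPS replicates 1 and 3, 196 and 456 without NC replicates 2 and 3, and 3435 without LPS replicate 2.

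After LPS ended, few genes passed against the control livers of day 7, which does not show a return to the control level. By edgeR's quasi-likelihood test 1652 of 16101 genes on day 9 and 1393 on day 11 had an unadjusted p under 0.05. On day 9, 69 genes passed (23 higher, 46 lower) and on day 11, 42 passed (11 higher, 31 lower); DESeq2 called 126 higher and 159 lower on day 9, and 74 and 88 on day 11. On day 9 S100a9 was higher by 4.22 ± 0.77, the metabolic genes Arrdc3 and Angptl8 rose by 2.96 and 2.47. The retinoic acid hydroxylase Cyp26b1 fell by 5.59 ± 0.78, Lpin1 by 2.69 and Ciart by 2.5. On day 11 Marco was higher by 2.15 ± 0.37 (adjusted p = 0.029), at 8.81 ± 2.52 against 1.99 ± 0.674 CPM, with Cpne8 and Atp11a at 1.39 and 1.26. The cell cycle inhibitor Cdkn1a, the stress gene Ddit4 and Per1 fell by 2.62 ± 0.41, 2.21 and 2.2 ± 0.35. Per1 also fell on day 9, by 1.84 (adjusted p = 0.0341), whereas Cry1 did not pass on day 9 (-0.23, adjusted p = 0.797) or day 11 (-0.36, adjusted p = 0.735).

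By list, 3 of 13 neutrophil markers rose on day 9 (8 adjusted over the list alone) and 1 of 20 macrophage markers on day 11 (14 rose and 1 fell adjusted over the list alone), with camera adjusted p = 2.47e-05 and 6.83e-10, and with an estimated correlation adjusted p = 0.254 and 0.194. Clock output genes had 2 falls in 18 on each day (adjusted p = 2.66e-08 and 1.27e-08, and adjusted p = 0.0928 for both with an estimated correlation). Gluconeogenesis genes had 2 falls in 22 on each day, Arg1 at -0.87 on day 9 and Tat at -1.78 on day 11 among them (adjusted p = 3.95e-16 and 4e-12, and with an estimated correlation adjusted p = 0.101 and 0.162). Fads2 did not pass on day 9 (-0.15, adjusted p = 0.94) or day 11 (-0.50, adjusted p = 0.781). The day-9 count fell to 15 and 17 without day-9 replicates 1 and 2 and to 22 without NC replicate 2. The day-11 count was 3 and 6 without day-11 replicates 3 and 1, 7 without NC replicate 2 and 72 without NC replicate 1. Of the 6 fits that left out 1 library, Per1 passed in 0 on day 9 and 2 on day 11, S100a9 in 2 on day 9, Cyp26b1 in 4 on day 9 and Marco and Cdkn1a in 2 on day 11. With all 48 libraries in the fit 37 and 10 genes passed.

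**Figure D4:**
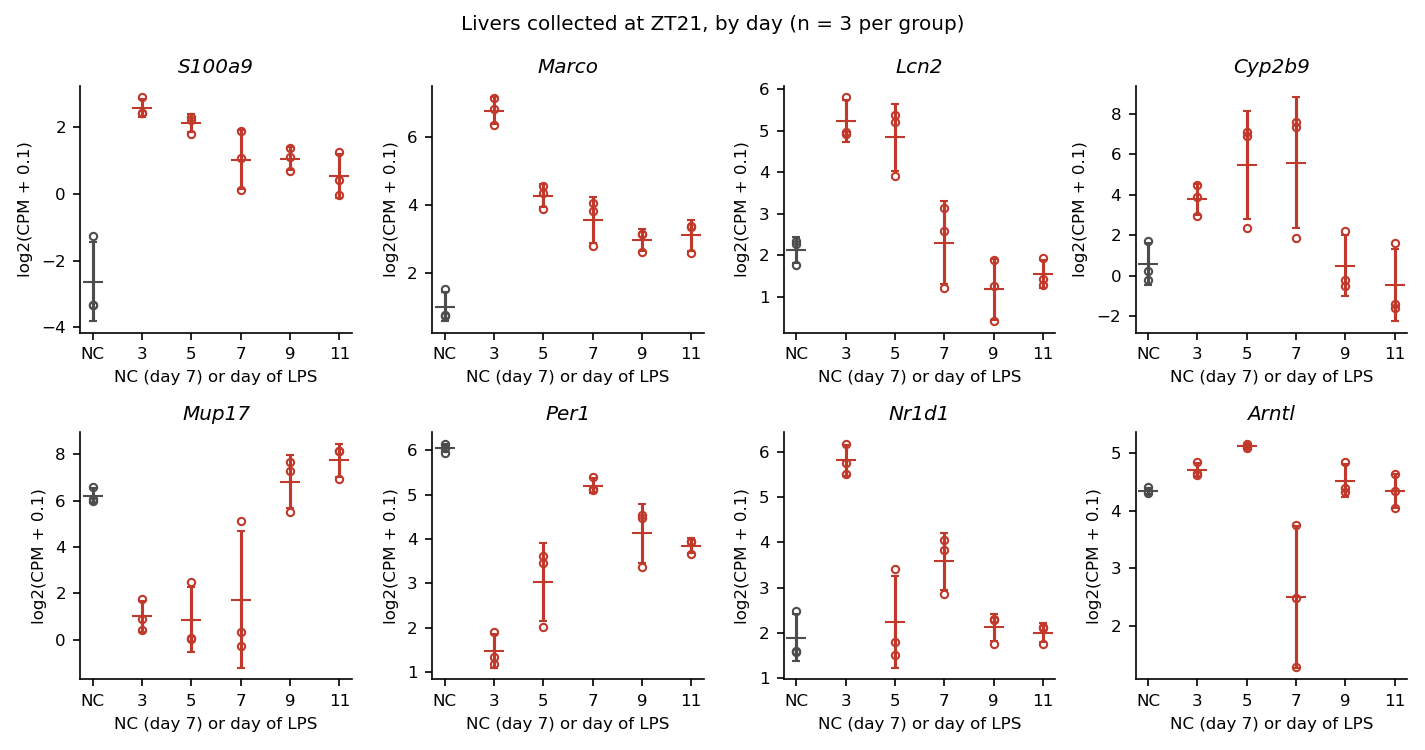
Level of 8 genes at ZT21 (log2 of CPM + 0.1, vertical axis) in NC livers of day 7 (grey) and LPS livers of days 3, 5, 7, 9 and 11 (red, horizontal axis); open points are libraries, dashes and bars are mean and SD of 3 libraries. Marco falls from 111 CPM on day 3 to 8.81 CPM on day 11 against 1.99 CPM in NC, and Per1 stands at 2.74 CPM on day 3 against 66.3 CPM in NC.

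**Figure D5:**
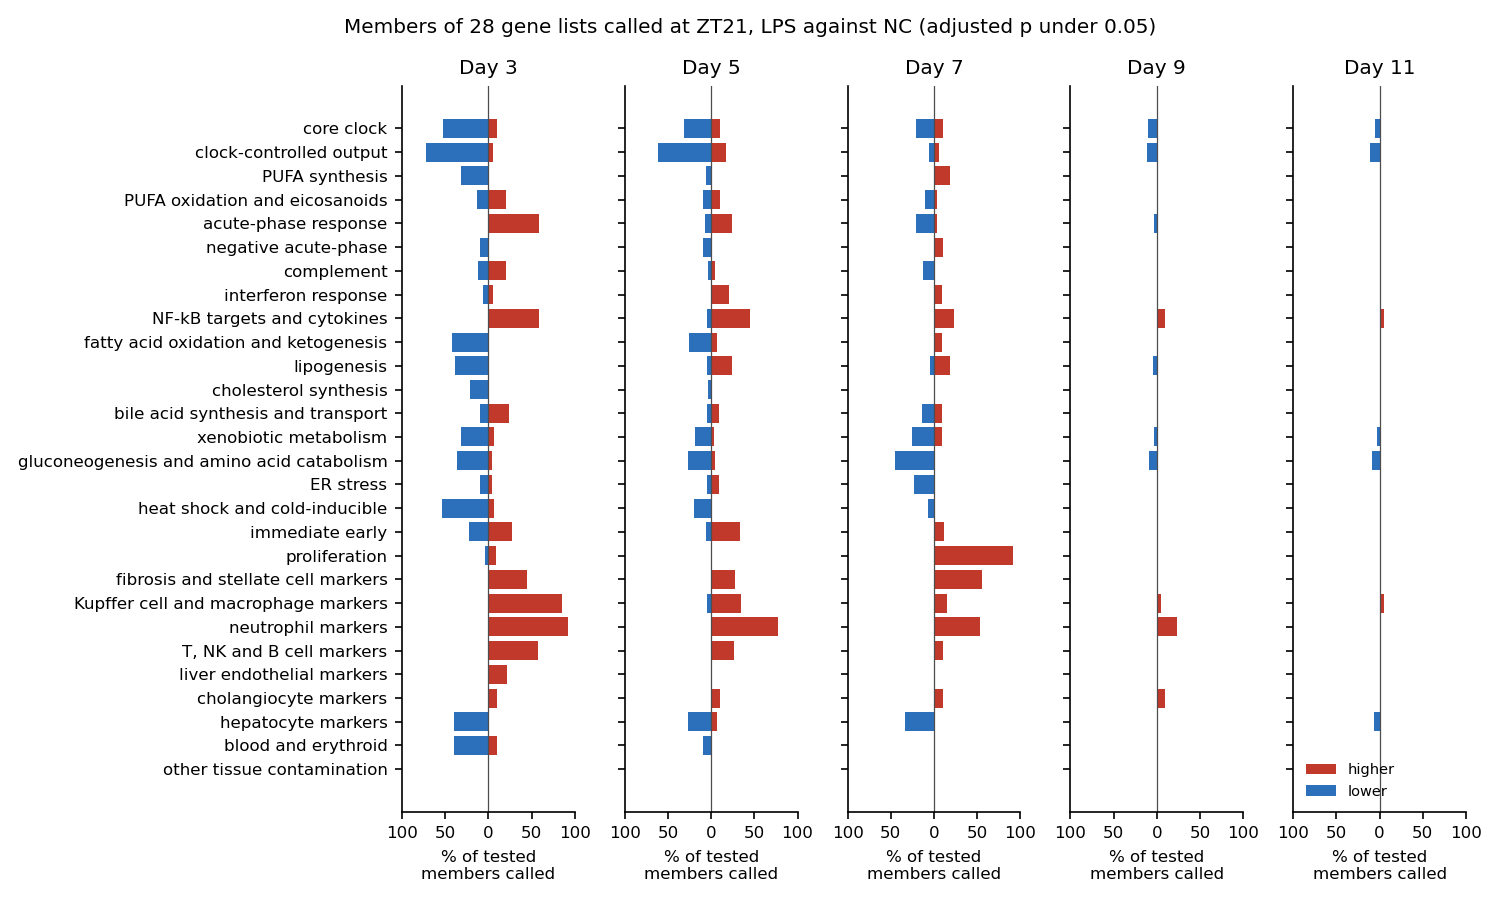
Share of the tested members of each of 28 gene lists (vertical axis) that were higher (red, to the right) or lower (blue, to the left) at adjusted p under 0.05, in percent (horizontal axis), for LPS against NC at ZT21 on each of 5 days. Macrophage markers are called in 17 of 20 on day 3, proliferation genes in 22 of 24 on day 7, and few members of any list on days 9 and 11.

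Within LPS libraries alone, a linear trend from day 3 to day 11 at ZT21 needs no control group. The clock reading of these libraries changed as well, from 9.43 and 5.27 h past the label on days 3 and 5 to -1.4, 1.63 and 1.27 h on days 7, 9 and 11, and the trend cannot be separated from it. Most acute-phase and macrophage genes fell over the days. Among the genes with the largest rises, Mup17 rose by 0.97 ± 0.16 on the log2 scale per day, Mup15 by 0.85, Mup7 by 0.70 and Ces2b by 0.57. Among the genes with the largest falls, Cyp2b9 fell by 0.65, Nipal1 by 0.57 and Lcn2 by 0.56 ± 0.06 per day (adjusted p = 8.86e-05). Of 29 acute-phase genes 22 fell (24 adjusted over the list alone), of 20 macrophage markers 16 fell (17 adjusted over the list alone), of 13 neutrophil markers 8 fell and of 22 NF-kB targets 12 fell and 1 rose. Fatty acid oxidation genes rose in 13 and fell in 2 of 31. Core clock genes rose in 7 and fell in 2 of 19 (10 and 2 adjusted over the list alone), with Per1 at 0.29 and Per3 at 0.36 per day, Nr1d1 at -0.40 and Npas2 at -0.53. Cry1 did not pass (0.04 per day, adjusted p = 0.245). In all 3298 of 16101 genes passed, 1698 rising and 1600 falling, and 2189 without day-11 replicate 1.

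Genes whose 3 LPS libraries all lay above or all below the 3 NC libraries were counted among the 16858 genes kept over all 48 libraries. On day 7 they made up 13.1% at ZT1, 19.8% at ZT5, 21.2% at ZT9, 20.8% at ZT13, 19.4% at ZT17 and 25.0% at ZT21. At ZT21 the shares were 40.4% on day 3, 32.8% on day 5, 18.4% on day 9 and 15.8% on day 11. Chance gives 10%.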

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

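Among the tests below, those of another collection time, of acute-phase strength, of blood and of female animals were chosen only after the result was seen. The LPS effect differed between times of day for 282 genes, by a test of that difference, with Hspa8 (adjusted p = 0.00137), Gpd2 (0.00274), P4ha1 and Hal (0.00338 each), Nrp1 (0.00413) and Arhgef37 (0.00526) in front. When treatment was shuffled within each ZT, 1 of 100 splits, the real one, gave as many genes, and the highest other gave 40. Such splits remove the averaged LPS effect as well, so they cannot judge chance for the difference between times alone. The 24 h rhythm differed between arms for 28 genes, led by Cyp2r1 (adjusted p = 0.0167), Nt5c2 (0.0229), Cntrl (0.0231), and Tedc2, Spaca6 and Igsf8 (0.0288 each). Here 2 of 100 splits gave as many, the real one and another with 41 genes. The same limit of the splits holds, so chance is not excluded for this number. The trend over days 3 to 11 at ZT21 was passed by 3298 genes, which excludes chance, as 1 of 100 splits reached it and the highest other gave 74.

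The livers of days 3 and 5 at ZT21 read 9.43 and 5.27 h past their label on the control clock, and those of days 9 and 11 less than 2 h past it. If the strength of the acute-phase response displaced clock genes, day-7 LPS libraries with the same acute-phase level should show it. The line through those 18 libraries predicts 0.323 h at the mean acute-phase level of days 3 and 5 (7.44), with an upper 95% bound of 1.16 h. Of the day-7 LPS libraries, only ZT17 replicate 1 (7.79) and ZT1 replicate 2 (11.6), which stood apart, lay above that level. The line also pools the times of day, so it cannot decide this explanation. Across them the relation was weak (Pearson r = 0.109, permutation p = 0.692; Spearman rho = 0.093, permutation p = 0.716; r = 0.210 without the 2 farthest libraries). Collection at, or a label for, another time of day is also a candidate explanation. The 200 rhythmic genes outside the clock lists placed the 6 libraries 7.03 h past the label on average, and no library by over 1.8 h from its clock-gene reading. A true displacement of the liver clock and its outputs during the first days of LPS, for example with changed feeding, would give the same values and was not tested apart from it.

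On day 7, 4 LPS libraries stood apart from the other 32, and many calls of the averaged effect, ZT13 and ZT21 rest on them. Sequencing depth is argued against: with all libraries thinned to the smallest total of 28.2 M, the gap to the nearest library was 34.7 against 35 before. Blood left in the tissue is argued against too, since 3 of the 4 had a mean of blood and erythroid genes inside the range of the other 14 LPS libraries and 0 lay above it. The mitochondrial share of counts was 4.38% in ZT1 replicate 2, 6.25% in ZT13 replicate 2, and 7.88 and 7.35% in ZT21 replicates 1 and 3. In the other 14 LPS libraries it ran from 7.33 to 11.6%, and what this reflects was not tested. A stronger or later response of those animals may be a cause and stays open, as the labels give no measure of illness per animal.

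Of 27 genes with known female bias in mouse liver 11 rose and 0 fell in LPS livers on day 7, and of 20 male-biased genes 3 fell and 0 rose. Female animals among the LPS mice are excluded by the values: 0 of 18 LPS libraries had Xist above the mean of 4 Y-linked genes, the highest Xist level being -1.66 and the lowest Y-linked mean 4.11 on the log2 CPM scale. The sex-biased genes were not a list fixed beforehand. Their pattern was first seen in these same libraries, so further members measured in them give no independent test. A shift of the sex-biased programme was tested on members that had not been looked at. There female minus male genes were higher in LPS by 1.36 on the log2 scale (95% interval 0.25 to 2.48, permutation p = 0.00461). Of these, 6 of 21 female-biased genes rose and 0 of 9 male-biased genes fell by edgeR; the median change of the 9 was -0.45. Without the 4 libraries apart the difference was 0.31 (permutation p = 0.0573), so the pattern rests in large part on those libraries, and its cause stays open.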

How the results depend on the processing

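The fits without the 4 libraries apart and against NC libraries of the nearest clock time were chosen only after the result was seen; all others were planned. Counts below refer to edgeR unless another tool is named. The cause of the changes was not tested, except that a stricter threshold leaves fewer calls by construction. Fits with fewer libraries gave fewer calls for some results and more for others. With RLE scaling no count moved by over 1.5 times. Without a filter on low counts the averaged effect had 1020 genes, ZT1 0, ZT9 23, ZT13 296 and the interaction 135. With a log2 change of at least 1 required the counts were 209 for the averaged effect, 34 at ZT9, 164 at ZT13, 640 at ZT21, 1133 and 862 rhythmic genes in NC and LPS, 18 for the difference in rhythm, 1360, 619, 665, 43 and 27 on days 3, 5, 7, 9 and 11, and 1 for the trend, whose unit is per day. With all 48 libraries in a single fit ZT1 had 239, ZT5 0, ZT17 7, day 9 37 and day 11 10. With the 6 compared libraries alone ZT1 had 0, ZT5 131, ZT13 0, ZT17 151 and ZT21 0 in both fits of day 7. A test of any difference between ZTs gave 3135 rhythmic genes in NC and 4188 in LPS. DESeq2 called 320 at ZT1, 50 at ZT5, 284 at ZT9, 1124 at ZT13, 52 at ZT17, 1725 for the interaction, 302 for the difference in rhythm, 285 on day 9 and 162 on day 11. Without the 4 libraries apart, where the 1 LPS library left at ZT21 is assumed to vary like the other groups, the averaged effect had 521, ZT1 0, ZT5 28, ZT9 394, ZT17 51, ZT21 2 and 3 in the day-7 and ZT21 fits, the interaction 108, the difference in rhythm 6 and day 9 109. Against NC libraries of the nearest clock time, in the fit of 48, days 3 and 5 had 1233 and 526, where NC of ZT21 gave 3258 and 1924. For days 9 and 11 the nearest was ZT21 itself, so 37 and 10 are the counts of that fit. Against the nearest NC, Per2 (0.62), Cry2 (0.0202), Hlf (0.14) and Ciart (0.47) on day 3 and Ciart (0.22) on day 5 turned positive. These clock genes took part in choosing the nearest NC, so their values are not independent of it. Of 12 lists past the threshold for the averaged effect 0 passed with an estimated correlation and 0 by fry, and of 81 list tests over the ZT21 days 1 and 42. Without Nr1d1 the day-7 clock time difference was -0.15 h. Of the named results, those that lost their call numbered 1 with RLE, 0 with DESeq2, 33 without the filter, 13 with all 48 libraries, 46 with 6 libraries, 48 without the 4 libraries apart, 24 in the comparison by nearest clock time and 361 of all removals of 1 library.

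The replicate numbers do not pair the libraries: pairs of libraries with the same number had a median correlation of 0.00487, 0 of 18 pairs of an LPS and an NC library of 1 ZT were above 0.1, and 17 of 48 libraries correlated best with their own number. With the replicate number as a block the averaged effect had 1489 genes, ZT1 0 and ZT17 2; no other count moved by over 1.5 times, and 16 named results, the 6 at ZT1 among them, went from below to above the threshold, with adjusted p up to 0.0704.

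Leaving out each library in turn, the averaged effect ranged from 949 without LPS ZT13 replicate 2 to 2461 without LPS ZT21 replicate 2, the interaction from 68 to 1429, the difference in rhythm from 1 to 72, and rhythmic genes from 3121 to 3753 in NC and 2123 to 2886 in LPS. ZT1 ranged from 0 to 563, with 390 without LPS replicate 3 and 1 without NC replicate 3, ZT5 from 1 without NC replicate 3 to 2, ZT9 from 0 to 68, with 16 and 29 without LPS replicates 1 and 3 and 20 without NC replicate 1, ZT13 from 111 to 720, ZT17 from 0 to 4, with 4 and 2 without NC replicates 1 and 3 and 3 without LPS replicate 3, and ZT21 from 64 to 2875. Days 3, 5, 7, 9 and 11 ranged from 2109 to 2563, 610 to 2481, 164 to 3435, 15 to 91 and 3 to 72, and the trend from 2189 without day-11 replicate 1 to 3815. Lists ranged from 8 to 13 and from 74 to 86. The day-7 clock time difference ranged from 0.112 to 0.418 h, and the readings of days 3, 5, 9 and 11 from 9.13 to 9.63, 4.15 to 5.85, 1.10 to 1.90 and 0.60 to 1.65 h. At this depth of at least 28.2 M counts per library, 16544 of 29331 genes had enough counts to be tested on day 7, and the others cannot be judged. Whether more libraries or more counts would add calls was not tested.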

Other observations

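The tests of other splits of the samples in this part were planned before the data were examined, and none was chosen only after the result was seen. Single genes of bile handling, ducts and eicosanoids passed on day 3 at ZT21, while the bile acid and eicosanoid lists as a whole did not (camera adjusted p = 0.779 and 0.408). On that day the bile acid sensor target Nr0b2 rose by 3.15 and the exporter gene Slc51b by 3.00, and in all 5 of 21 bile acid genes rose and 2 fell. Sox9, a transcription factor of bile ducts and of injured hepatocytes (GRCm38 chromosome 11, 112782224 to 112787760), rose by 1.77 ± 0.16 on day 3 (adjusted p = 4.44e-06) and by 1.86 on day 5 (adjusted p = 7.45e-06), and was the 1 of 10 cholangiocyte markers that passed on day 3. It stood at 4.69 CPM in NC, 16.1 and 17 CPM on days 3 and 5, and 6.38, 9.49 and 6.92 CPM on days 7, 9 and 11. Against NC libraries of the nearest clock time Sox9 passed on day 5 (1.31, adjusted p = 0.00739) and did not pass on day 3 (0.83, adjusted p = 0.055). Of 30 genes of polyunsaturated fatty acid oxidation 6 rose and 4 fell on day 3 (camera adjusted p = 0.408), with the eicosanoid genes Ptgds at 2.18, Alox5ap at 1.68 and Ptgs1 at 1.19 and the phospholipase Pla2g6 at -0.61.

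Single complement, early-response and blood cell genes also passed on day 3. Of 24 complement genes 5 rose and 3 fell, the rises including C1qa, C1qb and C1qc (1.09, 1.33 and 1.37), which macrophages make and which also stand in the macrophage list, and properdin, Cfp (1.61), while the list as a whole did not pass (camera adjusted p = 0.74). Of 18 immediate early genes 5 rose, with Egr1 at 5.67 ± 1.03 and Junb at 1.60, and 4 fell, with Dusp1 at -1.73 (camera adjusted p = 0.221). The haemoglobin genes Hba-a1, Hba-a2 and Hbb-bt fell by 2.56, 2.70 and 2.76, whereas the platelet gene Pf4 in the same list rose by 2.48 (camera adjusted p = 0.128). Against NC livers of ZT5, the nearest clock time, 0 of 11 blood and erythroid genes passed, with a median change of -0.50. With NC of ZT21 in the same fit 1 rose and 4 fell, with a median change of -0.54. In the comparison with ZT5, added after the data were seen, 1 immediate early gene and 2 complement genes rose and 0 fell, against 4 rises and 3 falls and 4 rises and 1 fall with NC of ZT21. Haemoglobin transcripts come from blood cells in the tissue, and how much blood each liver held is not recorded.

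Other splits of the same samples were counted for each remaining result. For the averaged effect on day 7 chance was excluded, with 1545 genes in the real split, reached by 1 of 100, and 1 gene in the highest other. For rhythmic genes it was excluded in NC, with 3719 genes against 12, and in LPS, with 2646 against 402, each reached by 1 of 100 splits. For the number of lists at ZT21 it was excluded, with 81 list tests against 72 in the highest other, reached by 1 of 100. The median other split gave 48, so a single list call at the preset correlation does not by itself exclude chance. For the 12 lists of the averaged effect chance was not excluded: 21 of 100 splits gave as many, the median other gave 9 and the highest 19. With 3 against 3 libraries the 10 splits are too few to judge. There the real and the highest other counts were 59 and 70 at ZT1, where 2 splits reached the real count, 2 and 0 at ZT5, 75 and 1 at ZT9, 526 and 5 at ZT13, 0 and 1 at ZT17, where 10 splits reached it, and 1473 and 373 at ZT21, and on days 3, 5, 7, 9 and 11 they were 3303 and 0, 1865 and 1, 1516 and 68, 69 and 19, and 42 and 1.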
